A study of Homo sapiens with 4 samples.

How the data were processed

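Poly(A) RNA was measured in 4 libraries of the H226 lung squamous cell carcinoma line, 2 with an inducible non-targeting hairpin (shControl) and 2 with an inducible hairpin against p63 (shp63), all after 6 days in 1 µg/mL doxycycline. Libraries were prepared with a stranded mRNA kit and sequenced on an Illumina instrument, per the labels' protocols and the series' design text. Reads were aligned by the authors to GRCh37 (hg19) with TopHat2 and counted per gene with HTSeq, and the submitters name DESeq2 as their test, per the series' design text. Per the submitters' processing notes the versions were TopHat2 2.0.13 and HTSeq 0.6.1, with bcl2fastq 1.8.4, FastQC 0.11.2, SAMtools 0.1.19, Picard 1.129 and Bowtie2 also named. The gene annotation and the strand setting of the counting were not given in the sources used here, so overlapping and antisense genes are uncertain. Paralogs that share reads are uncertain too.

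The deposited values are whole-number read counts per gene symbol, not normalized by the authors, for 25369 genes. Every column was matched to a sample by its name. Library totals were 53924761 and 52016366 counts for shControl and 53416511 and 51926832 for shp63, so that a gene at 1 CPM rests on about 50 reads per library. The most abundant gene, EEF1A1, took 1.45% and 1.40% of the counts in shControl and 0.971% and 0.989% in shp63, and the 10 most abundant genes took 5.30% to 5.58%.

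Counts were tested with edgeR 4.0.16 in R 4.3.3. Normalization used TMM factors, which ranged from 0.966 to 1.03. The filterByExpr step with its defaults (a minimum count of 10 and a minimum total of 15) kept 14901 genes and left out 10468. A quasi-likelihood model with robust dispersion and group as the only term was fitted to all 4 libraries, and p-values were adjusted by the Benjamini-Hochberg method with calls at an adjusted p under 0.05. The model's common biological coefficient of variation was 0.0308, with 2 residual degrees of freedom and a median prior of 18.8. Replicates this close give calls for small changes, so a test against a 1.5-fold change (glmTreat) was run as well. Standard errors of log2 fold changes were taken from the fold change and the square root of its F statistic. CPM values use the TMM factors, and errors beside them are standard deviations over the 2 libraries of a group. The p-values measure the spread between the 2 cultures of each group and no spread between hairpins, of which the labels name 1 per group.

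The test, the alternatives, 29 gene lists and the rule for named genes were fixed before the data were examined. The rule names TP63, TP73, TGFB2, RHOA, CDKN1A and MYC. It adds the 8 largest rises and 8 largest falls among called genes of at least 5 CPM on average whose groups do not overlap, and up to 2 members of smallest adjusted p per direction in each list. Members named to spell out a count of 5 or 6 were chosen after their values were seen. So were KRT5, TGM1, VIM, TGFB1, TGFB3, KRT1, DSG1, SPRR3 and genes whose values did not pass the test.

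The lists were those for basal epithelial and p63-associated genes, hemidesmosome, integrin and laminin genes, desmosome and cell junction genes, keratinocyte terminal differentiation, TGF-beta ligands, receptors and SMADs, TGF-beta response, actin and SRF targets, YAP and TAZ targets, mesenchymal and matrix genes, p53 targets, G1 and S phase, G2 and mitosis, interferon-stimulated genes, NF-kB and cytokines, NOTCH, WNT, growth factors and MAPK feedback, cholesterol and fatty acid synthesis, glycolysis and hypoxia, NRF2 and glutathione, unfolded protein and ATF4 response, mitochondrially encoded mRNAs, histones, and markers of mesothelium, fibroblasts, leukocytes, endothelium and lung epithelial or neuroendocrine cells. Some genes under this rule and 1 further list are not reported here. The lists were written from general knowledge and share some members, of which the mesenchymal and TGF-beta response lists share most (10 genes). The 28 lists with tested members were tested with camera (limma 3.58.1) against all other genes, with the preset correlation of 0.01 and, separately, an estimated one, and with fry, which asks whether a list's genes move on balance in one direction. Fry called 24 of the 28 lists at an adjusted p under 0.05.

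The test was tried on simulated counts for the 14901 genes with 200 changed genes, with means and dispersions taken from the fit to these libraries. In the data themselves 11033 genes were called, so the simulation does not give the error rate of those calls. For this comparison edgeR called 87.9% of 66 genes changed by 0.585 on the log2 scale, 92.5% of 67 changed by 1 and 97.0% of 67 changed by 2, with 18 calls among 14701 unchanged genes.

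Alternatives fixed in advance were DESeq2-style size factors (RLE), library totals without a composition factor, no low-count filter, a filter of 1 CPM in at least 2 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, each library left out in turn, and the estimated correlation. A crossed pairing of replicate numbers and a correction for GC content and transcript length (loess with a span of 0.3) were added after seeing the data. Coordinates, GC content and 3' untranslated regions came from GENCODE release 44 lifted to GRCh37, which may differ from the annotation behind the counts. It matched 21253 symbols directly and 1465 through older symbols, left 328 ambiguous and 2323 unmatched, and gave GC content and length for 14125 tested genes (94.8%). Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.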

Results

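Polyadenylated RNA was sequenced from H226, an established human lung squamous cell carcinoma cell line, carrying a doxycycline-inducible short hairpin RNA. One group of 2 cultures expressed a non-targeting hairpin (shControl) and the other group of 2 cultures expressed a hairpin against p63 (shp63). The submitters describe the 2 samples of each group as independent biological replicates. All 4 cultures received 1 µg/mL doxycycline for 6 days. The deposited table held read counts per gene, and the libraries summed to 51926832 to 53924761 counted reads. Reads were found for 17926 and 17953 genes in the shControl libraries and for 18137 and 18092 genes in the shp63 libraries. Between replicates the Pearson correlation of log2 CPM (read counts scaled to library size) across genes was 0.997 in both groups, against 0.959 to 0.962 between groups. The counts of each replicate pair differed by more than sampling noise, with a chi-square of 3.43 per degree of freedom for shControl and 3.74 for shp63, so all 4 libraries were kept as separate samples.

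The comparison asks which transcripts differ when the p63 hairpin replaces the non-targeting one. p63 is a transcription factor of the p53 family that maintains basal epithelial cells. Its gene, TP63, lies on chromosome 3 from 189349178 to 189615065 on the plus strand (GRCh37). TP63 had 7533 and 7364 reads in the shControl libraries and 1596 and 1530 reads in the shp63 libraries. Its mean normalised read count was 136 ± 0.798 CPM in shControl and 30.6 ± 0.116 CPM in shp63 (SD, n = 2 each), a 4.46-fold lower level (log2 fold change -2.16, SE 0.041). The adjusted p for TP63 was 2.28e-21 (edgeR quasi-likelihood test, Benjamini-Hochberg). These are counts of the whole gene, which do not separate the TAp63 and ΔNp63 isoforms.

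TP73, a relative of TP63, fell 2.89-fold from 8.17 ± 0.378 to 2.83 ± 0.162 CPM (SD, n = 2 each; log2 fold change -1.53, SE 0.101). MYC, a growth-promoting transcription factor, fell 4.17-fold from 114 ± 1.35 to 27.3 ± 0.269 CPM. TGFB2, the gene of the TGF-beta 2 ligand on chromosome 1 from 218518678 to 218617961, rose 2.33-fold from 49.1 ± 3.15 to 115 ± 2.99 CPM (log2 fold change 1.22, SE 0.045). CDKN1A, encoding the cell cycle inhibitor p21, rose slightly, from 341 ± 0.738 to 396 ± 8.47 CPM, and RHOA, a small GTPase of the cytoskeleton, fell slightly, from 403 ± 3.82 to 372 ± 10.5 CPM. The adjusted p was 6.92e-12 for TP73, 8.19e-21 for MYC, 2.24e-16 for TGFB2, 0.00229 for RHOA and 1.49e-06 for CDKN1A (edgeR quasi-likelihood test, Benjamini-Hochberg).

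**Figure D1:**
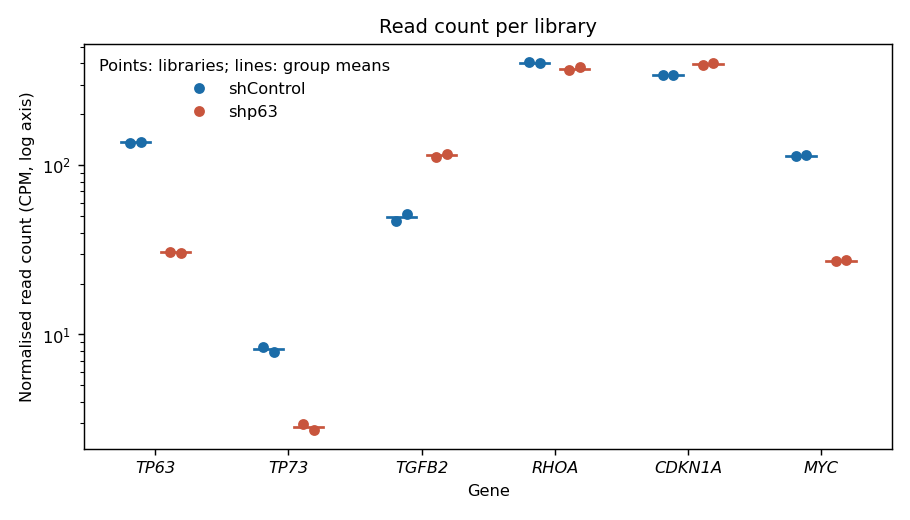
Normalised read count in CPM (log axis) of 6 genes in each library, with points for the 2 libraries of each group and lines for the group means. TP63 sits at 136 CPM in shControl and 30.6 CPM in shp63, MYC at 114 and 27.3 CPM, and TGFB2 at 49.1 and 115 CPM, while RHOA and CDKN1A differ little between groups.

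The largest rises among genes of at least 5 CPM on average were those of FER1L6 and IGFBP5. FER1L6, a member of the ferlin family, rose 52.7-fold from 3.70 ± 0.398 to 196 ± 0.248 CPM (SD, n = 2 each; log2 fold change 5.72, SE 0.055). IGFBP5, an insulin-like growth factor binding protein, rose 45.4-fold from 14.6 ± 1.08 to 663 ± 14.1 CPM (log2 fold change 5.51, SE 0.044). The cell surface glycoprotein gene CEACAM6 rose 34.9-fold and C8orf4 rose 29.0-fold. RASD1 rose 18.1-fold, RND1 rose 16.7-fold, the circadian transcription factor gene NPAS2 rose 15.4-fold and FRMD3 rose 13.9-fold. CEACAM6 has close paralogs, so its count depends on how reads shared between copies were assigned.

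The largest falls by the same rule were those of NGFR and NIPAL4. NGFR, a neurotrophin receptor of basal epithelial cells, fell 19.9-fold from 16.4 ± 0.535 to 0.821 ± 0.0617 CPM (SD, n = 2 each; log2 fold change -4.31, SE 0.111). NIPAL4 fell 18.5-fold. The atypical cadherin gene FAT2 fell 15.4-fold from 143 ± 16.3 to 9.29 ± 0.173 CPM, and RCSD1 fell 14.8-fold. SERPINB13, a serpin of squamous epithelia, fell 14.0-fold from 114 ± 4.21 to 8.12 ± 0.364 CPM. SERPINF1 fell 13.1-fold, CYP4F3 fell 9.63-fold, and the calcium-binding protein gene S100A2 fell 9.52-fold.

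Across the transcriptome, 11033 of 14901 tested genes differed between the groups at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), of which 5499 were higher and 5534 lower in shp63. Many of these differences were small, with a median absolute log2 fold change of 0.48. A test for a change beyond 1.5-fold called 3385 genes, 1894 higher and 1491 lower. Among the called genes, 1366 were higher and 977 lower by at least 1 on the log2 scale. The libraries of the groups did not overlap for 12877 tested genes (86.4%), where chance gives 33.3%. With 2 samples against 2, an exact two-sided permutation test of a single gene cannot give a p under 0.333, so the calls rest on the model's spread shared across genes. The labels name 1 construct per group, so effects of the hairpin and of its target are not separated in these libraries.

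**Figure D2:**
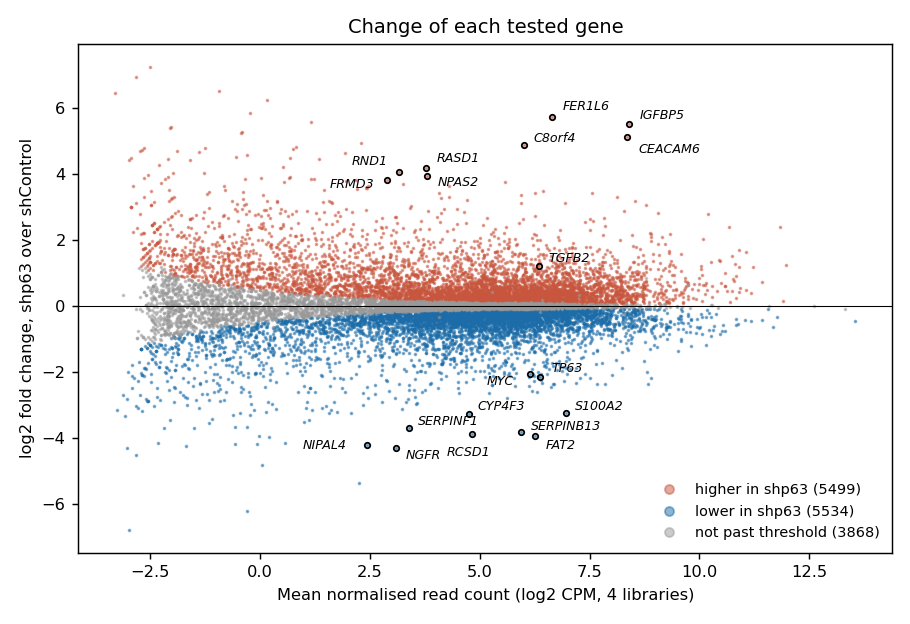
Change of each tested gene, as the log2 fold change of shp63 over shControl against the mean normalised read count (log2 CPM over 4 libraries), with genes called higher, called lower and not past the threshold in separate colours. The 5499 higher and 5534 lower genes lie on both sides of 0 across the range of expression, and TP63, TGFB2, MYC and the genes of largest rise and fall are named.

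Gene lists written before the data were examined were then tested as groups. In every list except those for YAP and TAZ targets and for NF-kB, the count of called members adjusted over the list alone equalled the count over all genes tested. None of the 12 lists called by camera with its preset correlation of 0.01 was called with a correlation estimated from these libraries, for which the lowest adjusted p was 0.262. That setting rests on 2 residual degrees of freedom, so it can hardly call a list. The G2 and mitosis list, with all 40 members lower, had an unadjusted camera p of 0.0347 there. Lists with estimated correlations below 0.01, such as NF-kB (0.00254) and leukocyte markers (-0.128), lost their calls too. For such lists the lost calls are no evidence against the list. Other called lists had estimated correlations far above 0.01, such as G1 and S (0.613), interferon (0.316) and G2 and mitosis (0.276). For these the preset correlation may give too small a p, so their preset calls are less certain.

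Genes of basal epithelium and genes known to follow p63 fell as a group. Of 30 tested members 23 were lower, 6 higher and 1 (GRHL2, 113 and 117 CPM) not past the threshold, with a median log2 fold change of -1.05. S100A2 fell from 224 ± 9.15 to 23.6 ± 1.07 CPM (SD, n = 2 each), and SFN, encoding the checkpoint protein 14-3-3 sigma, fell 4.54-fold from 255 ± 7.72 to 56.2 ± 0.183 CPM. The basal keratin gene KRT5 went from 757 to 148 CPM. AQP3, a water and glycerol channel gene, rose 1.61-fold, and ID3, an inhibitor of helix-loop-helix factors, rose 1.45-fold. Camera with Benjamini-Hochberg adjustment over 28 lists gave adjusted p = 1.44e-09, and adjusted p = 0.263 with an estimated correlation. TP63 and TP73 are themselves members of this list.

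Genes that anchor epithelial cells to matrix and to each other divided. Of 25 hemidesmosome, integrin and laminin genes 17 rose and 6 fell, with ITGA2 and LAMC1 not past the threshold (median log2 fold change 0.28). The 6 that fell were the hemidesmosome genes ITGA6, ITGB4 and COL17A1 and the basement membrane genes COL7A1, COL4A6 and NID1. COL17A1 fell 2.63-fold from 437 ± 3.40 to 166 ± 2.11 CPM (SD, n = 2 each), and COL4A6 fell 3.03-fold. The integrin subunit genes ITGB6 and ITGB5 rose 3.47-fold and 3.41-fold. Camera gave adjusted p = 0.00345 (Benjamini-Hochberg), and adjusted p = 0.263 with an estimated correlation. Desmosome and cell junction genes moved both ways, with 13 of 26 higher and 10 lower. Their median log2 fold change was 0.07 and their mean -0.13, opposite in sign, and camera's adjusted p was 0.95. The desmosomal cadherin genes DSG3 and DSC3 fell 4.42-fold and 7.72-fold, while CLDN7, a tight junction claudin gene, rose 1.99-fold, and EPCAM rose from 213 ± 1.32 to 384 ± 0.537 CPM.

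Of 30 listed genes of keratinocyte terminal differentiation 17 were tested. Of these 12 rose and 4 fell (KRT4, CSTA, KLK5 and KLK10), and TGM1 was at 5.86 and 5.80 CPM (adjusted p = 0.897, edgeR with Benjamini-Hochberg). The filter left out the others, among them KRT1 (0.0457 CPM in shControl and 0 in shp63) and DSG1 (0.202 and 0.157 CPM). Some rises were near the floor, such as SPRR3 from 0.0273 to 0.638 CPM. The median log2 fold change was 0.78, and ranged from 0.21 to 0.82 over the alternatives. Camera with Benjamini-Hochberg adjustment did not call the list (adjusted p = 0.129). S100A9 and S100A8, which encode the calprotectin subunits made by stressed keratinocytes and by myeloid cells, rose 2.47-fold and 2.70-fold. Leukocyte markers, CD14 among them at 6.17 and 43.9 CPM, were higher in the same libraries.

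Transcripts known to respond to TGF-beta rose as a group. Of 32 tested members 21 rose, 7 fell and 4 were not past the threshold (median log2 fold change 0.57). PMEPA1, a feedback inhibitor of the pathway, rose 4.52-fold from 173 ± 7.03 to 783 ± 16.9 CPM (SD, n = 2 each), and IGFBP3 rose 3.89-fold. TIMP3, a metalloproteinase inhibitor gene, and SNAI2, a transcription factor gene of epithelial-mesenchymal transition, fell 2.35-fold and 1.98-fold. Leukocyte and mesothelial markers were higher in the same libraries. Camera with Benjamini-Hochberg adjustment gave adjusted p = 1.73e-06, and adjusted p = 0.262 with an estimated correlation. Among 36 TGF-beta ligand, receptor and SMAD genes 21 rose and 9 fell, with a median log2 fold change of 0.30 that camera did not call (adjusted p = 0.0833, Benjamini-Hochberg). That call was near the threshold and changed with the tool and the filter. Beside TGFB2, LTBP3, encoding a latent TGF-beta binding protein, rose 1.91-fold, while BMP7 and SMAD5 fell 5.41-fold and 1.55-fold. The ligand genes TGFB1 and TGFB3 fell, from 7.28 to 4.99 CPM and from 2.22 to 0.968 CPM.

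Camera called none of the lists tied to the cytoskeleton, to YAP and TAZ or to mesenchyme, whose members moved both ways. Fry, which does not compare a list with other genes, called the YAP and TAZ list (adjusted p = 0.0101) and the mesenchymal list (adjusted p = 0.00192) upward but not the actin list (adjusted p = 0.201, Benjamini-Hochberg over the lists). Of 29 actin and SRF target genes 13 rose and 11 fell (median log2 fold change 0.09, camera adjusted p = 0.926, Benjamini-Hochberg). FHL2 and MYL9 rose 2.53-fold and 1.96-fold, and TLN1 fell 1.56-fold. Of 24 YAP and TAZ target genes 15 rose and 7 fell, or 15 and 8 adjusted over the list alone (median 0.37, camera adjusted p = 0.129, Benjamini-Hochberg). LATS2 rose 2.27-fold, and AXL, a receptor tyrosine kinase gene, fell 4.87-fold from 202 ± 1.23 to 41.6 ± 0.107 CPM (SD, n = 2 each). Of 27 mesenchymal and matrix genes 11 rose and 9 fell (median 0.10, camera adjusted p = 0.47, Benjamini-Hochberg). FN1, encoding fibronectin, rose 4.24-fold from 216 ± 6.81 to 917 ± 42.3 CPM and COL5A1 rose 3.31-fold, while MMP14 fell 1.66-fold. VIM had 7 reads or fewer in each library and was not tested.

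Genes of cell division fell nearly without exception. All 40 tested genes of G2 and mitosis were lower in shp63, with a median log2 fold change of -2.05. ASPM, a spindle pole gene, fell 5.16-fold from 338 ± 6.88 to 65.6 ± 1.36 CPM (SD, n = 2 each). CCNB1, encoding the mitotic cyclin B1, fell 5.09-fold from 243 ± 1.61 to 47.7 ± 0.787 CPM. Of 40 genes of G1 and S phase 38 fell (median -0.86). TYMS and RRM1, which supply DNA precursors, fell 2.65-fold and 2.11-fold. CCNE1, encoding cyclin E1, rose 1.24-fold (adjusted p = 0.00362, edgeR with Benjamini-Hochberg), but DESeq2 did not call it (adjusted p = 0.0698). E2F1 was at 27.0 and 26.2 CPM (adjusted p = 0.504, edgeR with Benjamini-Hochberg). Camera's adjusted p was 2.46e-50 for the G2 and mitosis list and 2.06e-14 for the G1 and S list (Benjamini-Hochberg). With an estimated correlation the adjusted p was 0.262 and 0.411.

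Of 36 tested p53 target genes 30 fell and 6 rose (median log2 fold change -0.55). The 6 that rose included CDKN1A, PMAIP1, GDF15, RPS27L and IGFBP3. BTG2, an antiproliferative gene, fell 3.14-fold from 104 ± 2.01 to 33.1 ± 0.509 CPM (SD, n = 2 each), and GDF15, a stress cytokine gene, rose 2.05-fold. Camera gave adjusted p = 1.44e-05 (Benjamini-Hochberg), and adjusted p = 0.262 with an estimated correlation.

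Inflammatory and antiviral genes rose. Of 28 tested NF-kB and inflammatory cytokine genes 21 rose, or 22 adjusted over the list alone, and 4 fell, with a median log2 fold change of 0.78. PTGS2, encoding cyclooxygenase-2, rose 6.38-fold from 9.68 ± 0.859 to 61.7 ± 1.22 CPM (SD, n = 2 each), and BIRC3, an inhibitor of apoptosis, rose 4.51-fold. The 4 that fell were IL1A, IL1B, CSF1 and NFKB1. Of 37 interferon-stimulated genes 28 rose, 3 fell (OAS3, SAMD9 and TRIM22) and 6 were not past the threshold, with a median of 0.54. IFITM1 and IFIT2 rose 1.68-fold and 2.25-fold. Camera's adjusted p was 0.000156 for the NF-kB list and 0.000255 for the interferon list (Benjamini-Hochberg), and the adjusted p was 0.262 and 0.529 with an estimated correlation. Leukocyte markers rose in the same libraries, as given with the marker lists.

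Signalling lists moved both ways. Of 24 NOTCH pathway genes 12 fell and 6 rose (median log2 fold change -0.06, camera adjusted p = 0.21, Benjamini-Hochberg). The receptor gene NOTCH1 and the ligand gene DLL1 fell 4.51-fold and 4.12-fold, while the protease gene ADAM10 and HES1 rose 1.88-fold and 1.51-fold. Of 31 WNT pathway genes 15 rose and 9 fell (median 0.11, camera adjusted p = 0.0777, Benjamini-Hochberg). WNT7B and FZD1 rose 2.23-fold and 2.75-fold, and FZD6 and WNT4 fell 2.55-fold and 2.22-fold. Of 34 growth factor receptor, ligand and MAPK feedback genes 18 rose and 12 fell (median 0.43, camera adjusted p = 0.31, Benjamini-Hochberg). The MAPK phosphatase gene DUSP4 rose 5.84-fold from 49.3 ± 0.405 to 288 ± 1.15 CPM (SD, n = 2 each), IER3 rose 4.90-fold, and FGFR2 fell 3.31-fold.

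Metabolic lists fell where they concerned lipids and redox balance. Of 34 cholesterol and fatty acid synthesis genes 26 fell, 5 rose (IDI1, TM7SF2, SREBF1 and ACSL3 among them) and 3 were not past the threshold (median log2 fold change -0.61). HMGCS1 and SQLE, enzymes of sterol synthesis, fell 2.52-fold and 2.29-fold. Of 30 NRF2 target and glutathione genes 23 fell, 4 rose (HMOX1, TXNRD1, GSR and ABCC3) and 3 were not past the threshold (median -0.63). SLC7A11, the cystine transporter gene, fell 2.94-fold from 190 ± 3.28 to 64.7 ± 2.24 CPM (SD, n = 2 each), and GPX2, a glutathione peroxidase gene, fell 5.64-fold. This list holds the near-identical paralogs AKR1C1 and AKR1C2, whose counts depend on read assignment. Camera's adjusted p was 3.99e-09 for the lipid list and 1.07e-07 for the NRF2 list (Benjamini-Hochberg), and the adjusted p was 0.265 and 0.262 with an estimated correlation. Of 33 glycolysis and hypoxia genes 19 rose and 11 fell (median 0.16, camera adjusted p = 0.129, Benjamini-Hochberg). HK2 and the lactate exporter gene SLC16A3 rose 2.05-fold and 2.03-fold, while ENO1 and ALDOC fell 1.37-fold and 1.59-fold.

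The unfolded protein and ATF4 list moved both ways, with 17 of 32 genes higher and 15 lower. Its median log2 fold change was 0.14 and its mean -0.07, opposite in sign, and camera did not call it (adjusted p = 0.894, Benjamini-Hochberg). XBP1, a transcription factor gene of the endoplasmic reticulum stress response, rose 3.28-fold from 186 ± 1.81 to 611 ± 4.66 CPM (SD, n = 2 each), and the chaperone gene DNAJB9 rose 2.38-fold. PSAT1, an enzyme of serine synthesis, fell 2.96-fold from 236 ± 0.786 to 80.0 ± 3.97 CPM. Of 13 tested histone genes 3 rose, 3 fell and 7 were not past the threshold (camera adjusted p = 0.95, Benjamini-Hochberg), with a median of 0.01 and a mean of -0.15. With any 1 library left out the histone median was -0.59 to -0.24. HIST2H2BE rose 1.96-fold and HIST1H1C fell 1.36-fold. Replication-dependent histone mRNAs lack poly(A) tails, so a poly(A) library holds little of them. The list of 13 mitochondrially encoded mRNAs was not analysed here.

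Markers of other cell types were measured in the same libraries. Of 18 listed leukocyte markers the filter kept 8. Of these 6 rose and 2 (FCER1G and LAPTM5) were not past the threshold (median log2 fold change 1.76). CD14 rose 7.11-fold from 6.17 ± 0.435 to 43.9 ± 1.82 CPM (SD, n = 2 each), and CD68 rose 4.78-fold from 6.62 ± 0.516 to 31.6 ± 0.864 CPM. Of 20 listed mesothelial markers the filter kept 11, of which 9 rose and 2 (BNC1 and BCAM) fell (median 0.61). MSLN, encoding mesothelin, rose 2.51-fold from 132 ± 2.86 to 330 ± 5.99 CPM, and KRT18, a keratin gene of simple epithelia, rose 2.62-fold. Camera's adjusted p was 0.000516 for the leukocyte list and 0.00101 for the mesothelial list (Benjamini-Hochberg), and the adjusted p was 0.262 for both with an estimated correlation. Without the low-count filter camera no longer called the mesothelial list (adjusted p = 0.0781, Benjamini-Hochberg). With DESeq2, which tested more genes of low count, the leukocyte median was 1.16. Of 6 endothelial markers 4 rose, with CDH5 at 56.7 and 187 CPM, and VWF fell 3.57-fold (median 0.95, camera adjusted p = 0.132, Benjamini-Hochberg). Of 10 fibroblast markers 4 rose and 3 fell (median 0.04, camera adjusted p = 0.207, Benjamini-Hochberg), with FBLN1 2.21-fold higher and COL1A1 1.40-fold lower. Of 7 lung epithelial and neuroendocrine markers 3 fell and 1 rose (median -0.65, camera adjusted p = 0.614, Benjamini-Hochberg). CHGA was at 1.46 and 0.235 CPM and MUC5B at 5.29 and 8.11 CPM.

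**Figure D3:**
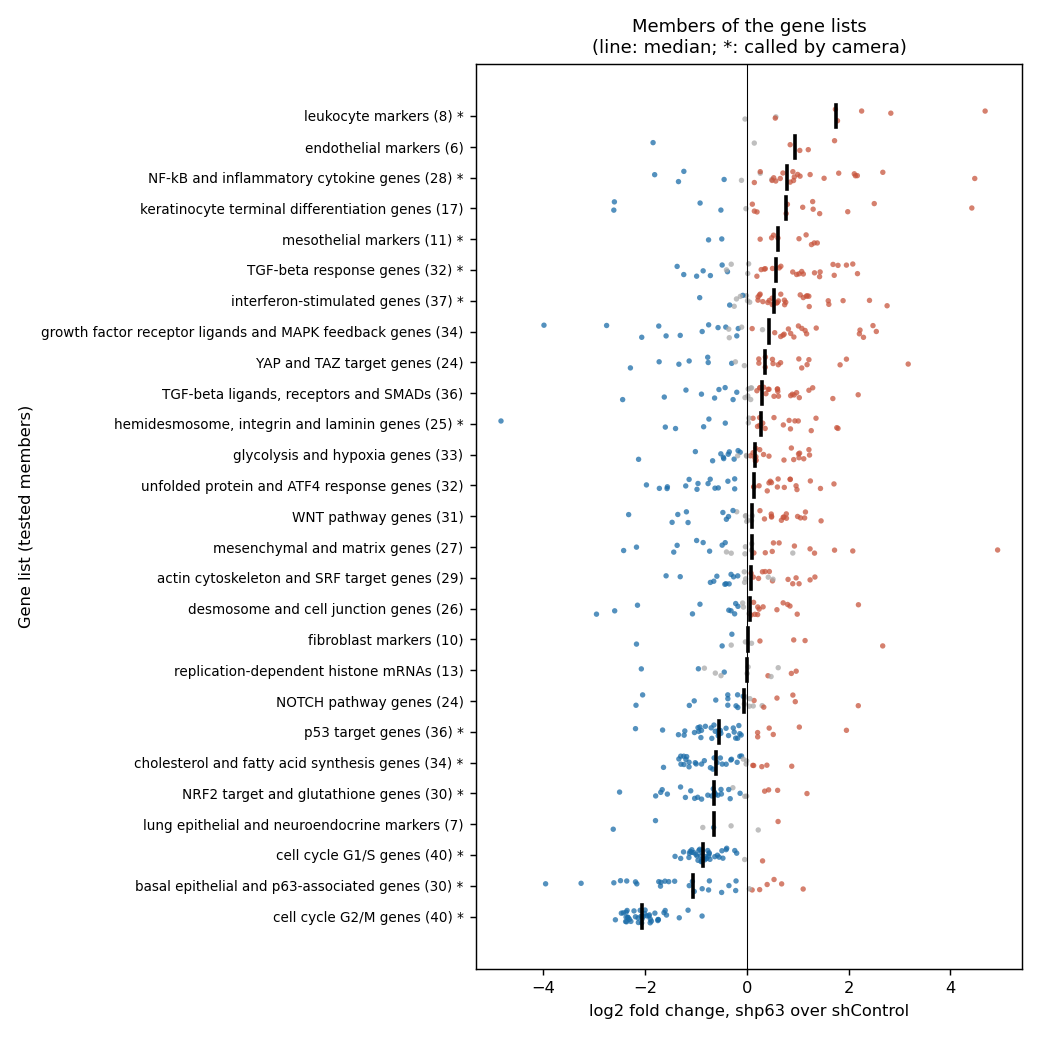
Log2 fold change (shp63 over shControl) of the tested members of 27 gene lists, with a point per gene coloured when called higher or lower and grey when not past the threshold, and a black line at each list's median. The G2 and mitosis list lies wholly below 0 with a median of -2.05, the basal list has a median of -1.05, and the NF-kB list a median of 0.78. An asterisk marks the 12 lists that camera called with its preset correlation.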

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

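The GC and length correction and the crossed pairing were chosen after the data were seen, and the other alternatives before. TP63's log2 fold change ranged from -2.24 to -2.13 over 13 alternatives. The count of called genes ranged from 9373 (DESeq2) to 11387, and from 10353 to 10548 with 1 library left out, where the lone library of a group is assumed to vary like the other group. The 1.5-fold count ranged from 2305 to 3478. Library totals alone moved the median gene by -0.088 and gave 4658 higher and 6591 lower genes (41.4% higher, against 49.8%), with 34 calls changing sign. The GC and length correction moved it by -0.043 and gave 5226 higher and 5987 lower genes (46.6% higher), with 119 calls changing sign. Of 1546 values of named genes under the alternatives, 1544 kept their direction and side of the threshold. CCNE1 missed it with DESeq2 (0.31, adjusted p = 0.0698), and HIST1H1C missed it without shp63 replicate 1 (-0.30, adjusted p = 0.055).

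With an estimated correlation camera called none of the lists: basal (-1.05, adjusted p = 0.263), hemidesmosome (0.28, 0.263), TGF-beta response (0.57, 0.262), p53 (-0.55, 0.262), G1 and S (-0.86, 0.411), G2 and mitosis (-2.05, 0.262), interferon (0.54, 0.529), NF-kB (0.78, 0.262), lipid synthesis (-0.61, 0.265), NRF2 (-0.63, 0.262), mesothelial (0.61, 0.262) and leukocyte (1.76, 0.262). These medians do not change with that setting, which has little power with 2 residual degrees of freedom. The TGF-beta ligand list became a call without the low-count filter (0.35, adjusted p = 0.0255), with limma-voom (0.30, 0.041) and after GC and length correction (0.29, 0.0452). Glycolysis became a call with DESeq2 (0.17, 0.0444) and with the crossed pairing (0.16, 0.0496), as did YAP and TAZ targets with the crossed pairing (0.37, 0.0352). The mesothelial list lost its call without the filter (0.48, 0.0781). Medians of many lists that camera did not call were unstable. Over the alternatives the keratinocyte differentiation median ranged from 0.21 to 0.82, WNT from 0.02 to 0.32, growth factor and MAPK from 0.11 to 0.55, lung epithelial and neuroendocrine from -0.78 to -0.21, and histones from -0.59 to 0.42. With 1 library left out these ranged from 0.45 to 0.82, 0.14 to 0.32, 0.36 to 0.46, -0.76 to -0.50 and -0.59 to -0.24. Medians nearer 0 moved as well, mesenchymal from -0.03 to 0.11, fibroblast from -0.07 to 0.26, NOTCH from -0.16 to -0.02, unfolded protein and ATF4 from 0.03 to 0.17, actin from -0.08 to 0.09, desmosome from -0.02 to 0.07 and glycolysis from 0.07 to 0.17, and the endothelial median fell to 0.55 with DESeq2. Leaving out shControl replicate 2 took the mesenchymal median to -0.0021 and the fibroblast median to -0.07, and leaving out shp63 replicate 1 took the fibroblast median to -0.07 and NOTCH to -0.13. NOTCH was -0.11 and unfolded protein 0.09 without shControl replicate 1. The tested members of a list can differ between settings, with 14901 genes tested in the main fit, 16278 with DESeq2 and 19719 without the filter. The filter was also rerun with each library left out. How far this accounts for the changed medians was not tested. Camera's calls of the other 24 lists held under all alternatives with the preset correlation.

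The replicate numbers were not treated as pairing the samples, since the labels give no shared day. The replicate block called 10858 genes, 5408 higher and 5450 lower, of which 10834 are also calls without it, and it changed the call of no list or named gene. Deviations of same-numbered libraries correlated at -0.11 across all tested genes and at -0.49 across the 11048 genes of at least 5 CPM, and replicate 1's deviation correlated with GC content at -0.21 in shControl and 0.34 in shp63 across genes. The crossed pairing called 11387 genes, 5659 higher and 5728 lower. Depth limits genes under about 1 CPM, of which many were removed by the filter.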

Other observations

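The gene families and sets of related genes in this part were chosen after the data were seen, and of the tests of explanations that of normalization for the p53 targets was chosen only after its result was seen. Genes were grouped by the letters that open their symbols, which gave 251 families of at least 8 tested members. Camera with the preset correlation called 30 of them (Benjamini-Hochberg). With an estimated correlation, which rests on 2 residual degrees of freedom, camera called none, and the adjusted p was 0.884 for each family named here. Ribosomal protein genes fell almost in unison. Of 78 tested ones 75 were lower in shp63 and 1 (RPS27L) higher, with a median 1.46-fold fall, and 75 were lower under library totals, RLE factors, DESeq2 and the GC and length correction alike. The RPL family had adjusted p = 1.02e-12 (camera, Benjamini-Hochberg). Nucleoporin genes fell in 20 of 21 cases (median log2 fold change -0.57, adjusted p = 1.59e-05), centrosomal CEP genes in 28 of 34 (-0.53, 3.58e-05), and all 9 tested genes named MCM with a number, which act in DNA replication and repair, fell (-0.82).

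Genes of the vacuolar proton pump, ATP synthase and the TMED family went the other way. Of 22 tested subunit genes of the vacuolar proton pump 18 rose (median 1.39-fold), of 18 ATP synthase genes 14 rose, and of 9 TMED cargo receptor genes 8 rose (median 1.61-fold). Under library totals the counts were 17, 12 and 8. The ATP family as a whole had adjusted p = 1.59e-05 and the TMED family 0.00181 (camera, Benjamini-Hochberg). Mucin genes rose in 9 of 11 cases (median log2 fold change 1.27, adjusted p = 0.0131), with MUC1 at 42.1 and 180 CPM. All 8 tested PSG genes of the pregnancy-specific glycoproteins were higher (median 1.92, adjusted p = 0.000882), of which DESeq2 called 7. All 15 PCDHB protocadherin genes were higher too (median 1.25, adjusted p = 0.0055), of which 14 were called under library totals and 10 by DESeq2. PSG and PCDHB genes are families of related copies that can share reads, so the counts of single members are uncertain. The protocadherin cluster also gave the strongest block of 50 neighbouring genes in the genome, on chromosome 5 from 138732252 to 140734588 (GRCh37), with 36 of 50 genes higher, 21 of the 50 being protocadherins, and a median log2 fold change of 0.71.

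Most p53 target genes fell although CDKN1A rose. The list's highest median under library totals or RLE factors was -0.55. Those settings moved the median gene by only -0.088 and 0.0064, so they could hardly bring the list near 0. This comparison therefore does not decide whether scaling between libraries plays a part. Trends with GC content or transcript length do not explain the fall, since the list's median was -0.56 after that correction. Only 2 members, SFN and PERP, are shared with the basal list, so leaving them out could hardly move the median. The 34 others had a median of -0.55, 28 of them lower. A candidate explanation is loss of p63 at promoters it shares with these targets. This hypothesis was not tested, and an effect of the hairpin apart from p63 stays open.

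With 11033 of 14901 genes called, the change reached most of the tested transcriptome. A copy number difference between the cultures over much of the genome would shift many blocks of neighbouring genes together. The share of 273 blocks with an absolute median log2 fold change of at least 0.4 was 0.00366. A difference that wide was not seen, but one confined to single regions is not excluded. Below that bound lay block medians of -0.37 and 0.34 on chromosome 4 and 0.31 on chromosome 21. A few abundant genes did not take over the libraries. The share of counts in the 10 most abundant genes differed by -0.237 percentage points (shp63 minus shControl). Direct pairing of the hairpin's seed with 3' untranslated regions would enrich a 7-base word of the TP63 transcript among genes that fell. The hairpin's sequence is not in the labels, so 5400 such words were searched. The largest excess over matched unchanged genes, as a share of genes, was 0.0423, against 0.0423 among genes that rose. Pairing with a large share of the genes that fell was not seen, but the search cannot detect pairing with a small share. A broad biological response to p63 loss, with slower division, is a hypothesis that may account for the wide change. Seed pairing with fewer genes, the hairpin's passenger strand, indirect hairpin effects and differences between the lines stay open with 1 construct per group.

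Leukocyte markers rose, with CD14, CD68 and ITGB2 at 43.9, 31.6 and 34.3 CPM in shp63. Leukocytes in the cultures would bring PTPRC, their common surface antigen, but its highest level in a shp63 library was 0.154 CPM, and TYROBP had 0 reads in every library. In shControl 5 of the 8 tested leukocyte markers and 10 of the 11 tested mesothelial ones were at 1 CPM or more. The lists hold 18 and 20 markers, and the filter had left out those of low count. The shares of tested markers are therefore no measure of how many H226 expresses. Expression of these markers by the tumour cells is a candidate explanation. Why these genes rose was not tested.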
